A study of Homo sapiens with 6 samples.

How the data were processed

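Genomic DNA of H460 cells carrying Cas9 and the GeCKO v2 library was sequenced over the integrated guides in 6 libraries, 3 untreated controls and 3 given 4 Gy of ionizing radiation, per the labels. Group and replicate number came from the sample labels. For each of 123411 guide IDs the deposited files gave the guide sequence of 20 bases, read counts and fractions. Per the file headers, the counts are cumulative over reads with 0, up to 1 and up to 2 mismatches, and they are whole numbers that were not normalized. Per the file headers, each fraction is a count divided by the column total, and the fractions were used only to check this. The counting program and its settings are not given in the sources used here. Reads with 1 or 2 mismatches added 7.97% to 9.12% to the exact matches. Exact matches were the main counts.

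The 123411 IDs held 119461 different sequences, and 6920 IDs shared their sequence with another ID. Reads of such a sequence were spread over its IDs in the deposited counts, so its counts per ID are uncertain. Single-ID guides numbered 61649 in sub-library A and 54842 in sub-library B, as the ID prefix assigns them. The last 1000 sequences of both sub-libraries are the same and stand in the same order. In the published library such shared controls are non-targeting, but the files do not name them. They served as an alternative scaling set and in a test of drift in the closing section, and both uses rest on that background. The files do not pair guide IDs with genes, and the reference table used here pairs gene identifiers with symbols but holds no guide sequences. The planned gene-level tests, gene lists and essential-gene values were therefore not run, and results are given per guide. At most 2 guides are named in each direction for the same reason.

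Guides were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors, filterByExpr with a minimum count of 10, 3 control against 3 irradiated libraries without covariates) and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 was an alternative. The rule for named guides, fixed before the data were examined, took the 5 guides with the smallest edgeR p in each direction in the fit over all guides, of which the first 2 in each direction are printed. Fixed at the same time were this design, the measures of representation and agreement, and the alternatives for scaling, count filter, replicate block, threshold, tool, shared sequences, depth and left-out libraries. Chosen after seeing the data were the fits within sub-library A and sub-library B, the fits without the 2 libraries low in sub-library A, counts with mismatches and counts summed over the IDs of a sequence. The fits within a sub-library used single-ID guides and library sizes from those guides.

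The guide test was tested on simulated counts drawn from the means, depths and spread of these libraries, with 50 guides changed at each of 2, 4, 8 and 16-fold. Over all guides 0%, 0%, 2% and 6% of them were recovered, and within sub-library A 10%, 52%, 84% and 82%. Of the unchanged guides, 1 of 110695 was called over all guides and 25 of 52635 within sub-library A, where they made up 18.0% of the 139 simulated calls at an adjusted p of 0.05. Each guide had 1 spread for both groups, and guides were drawn independently of each other, so these rates may not carry over to the data.

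Guides with 0 reads, the Gini index and the share of reads in the top 1% of guides were computed per library and compared by 2-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. For sub-library A these values were taken after random thinning of each library to 1189544 reads, the smallest sub-library A total. Correlations used log2(CPM + 1) over 110586 guides with at least 10 reads, scaled to the smallest library, in at least 3 libraries. Those of thinned sub-library A took all its single-ID guides without this filter. Counting noise between pairs of libraries was measured as a chi-square per degree of freedom over guides with at least 50 reads in the pair. Shares of reads carry 95% Wilson intervals, and a guide without reads in a group was set to a floor of 3 reads over that group. Depth ranged from 32278033 to 36928391 exact reads per library, and from 1189544 to 17353489 reads on single-ID sub-library A guides, so that sub-library A was measured least precisely in control replicate 1 and irradiated replicate 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these values. The 10 ways of splitting the 6 libraries into 3 and 3 were each fitted in the same way.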

Results

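The screen used H460, an established human non-small cell lung cancer line that expressed the nuclease Cas9 and carried GeCKO v2, a pooled genome-wide knockout library of guide RNAs. GeCKO v2 comes in 2 parts, called sub-library A and sub-library B here, and each integrated guide marks the cells whose target it cuts. Guide sequences were read from genomic DNA of 3 untreated control libraries and 3 libraries from cells given 4 Gy of ionizing radiation. The series title names the search for genes of radiation resistance as the purpose, so the comparison asked which guides became more or less abundant after irradiation. Each library held counts for 123411 guide IDs, of which 65383 belonged to sub-library A and 58028 to sub-library B. Reads that matched a guide exactly numbered 32665821, 34725242 and 36813057 in control replicates 1 to 3. Irradiated replicates 1 to 3 held 34651511, 36928391 and 32278033. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

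Sub-library A was scarce in 1 library of each group. Among reads on guides with a single ID, its guides took 3.85% in control replicate 1 (95% Wilson interval 3.84 to 3.85) and 6.13% in irradiated replicate 3 (6.12 to 6.14). The other 4 libraries held 41.3% (control replicate 2), 49.5% (control replicate 3), 47.2% (irradiated replicate 1) and 49.6% (irradiated replicate 2). The median sub-library A guide had 10 reads in control replicate 1 and 15 in irradiated replicate 3, against 111 to 153 elsewhere. Sub-library B guides had medians of 486 and 468 reads in those 2 libraries and of 168 to 239 in the other 4. Intervals and floors given here cover counting error only, because reads without molecular identifiers are not independent molecules.

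**Figure D1:**
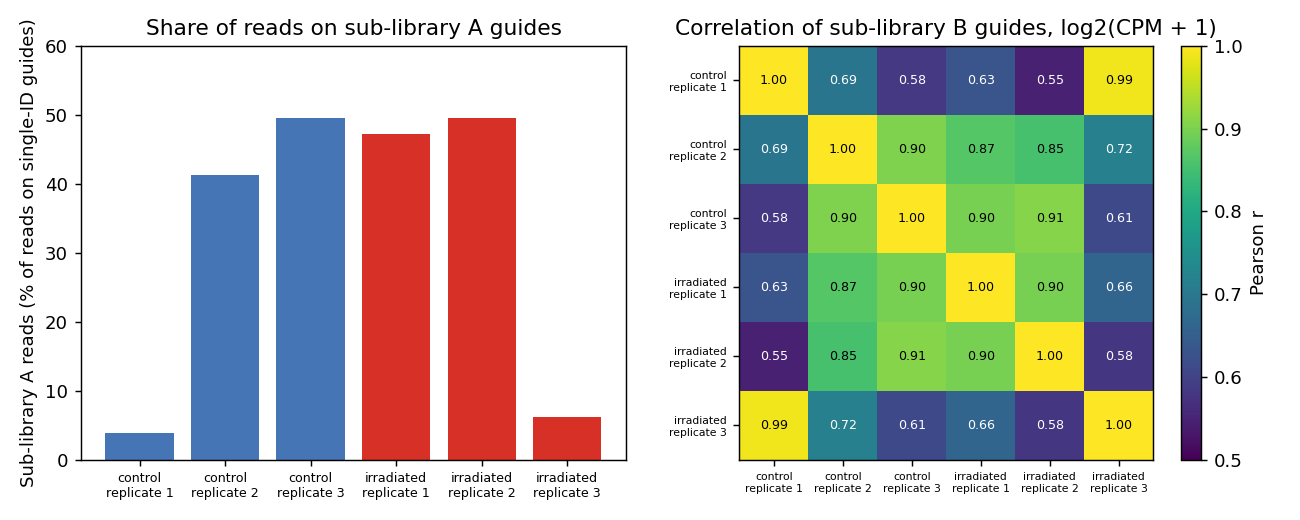
The left panel plots sub-library A reads as a percentage of the reads on single-ID guides in each of the 6 libraries, with controls in blue and irradiated libraries in red, and the right panel gives Pearson r of log2(CPM + 1) over sub-library B guides for each pair. Control replicate 1 and irradiated replicate 3 sit at 3.85% and 6.13%, and their sub-library B guides correlate at 0.988.

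Libraries were compared by the correlation of log2(CPM + 1), where CPM is counts per 1e6 reads, across guides, which are not independent replicates. Over all guides the mean r was 0.511 within controls, 0.493 within irradiated libraries and 0.629 between the groups. Control replicate 1 and irradiated replicate 3 formed the closest pair at 0.986, whereas control replicates 1 and 3 reached 0.198. Sub-library B showed the same closest pair (r = 0.988), and for that pair the chi-square per degree of freedom over guides was 1.95. Pure counting noise of independent molecules gives 1, and the next lowest sub-library B pair stood at 33.2. The 2 libraries were kept as samples of their own groups, but reads are not independent molecules, so the ratio does not show that their sub-library B parts came from separate DNA. In sub-library A, thinned to 1189544 reads in every library, mean r was 0.906 within controls, 0.879 within irradiated libraries and 0.865 between them. There the lowest r within a group, 0.876, exceeded the highest between groups, 0.872. Without thinning the ranges overlapped, at 0.845 to 0.857 within irradiated libraries and 0.792 to 0.858 between groups. The thinned values took all 61649 single-ID guides of sub-library A, the others only those passing the read filter. They thus differ in guides as well as depth, and the separation cannot be credited to equal depth alone. Restricting the comparison to sub-library A was chosen after seeing the data.

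More sub-library A guides were missing from the irradiated libraries at equal depth. Of 61649 sub-library A guides with a single ID, 8692 ± 307 (SD, n = 3) had no read in the controls and 12003 ± 887 (SD, n = 3) had none after irradiation. The lowest irradiated library, at 11348 guides, lay above the highest control at 9002. A 2-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Without thinning the groups overlapped, with 5468 ± 3061 guides missing in controls and 7927 ± 1638 after irradiation (SD, n = 3 each; exact p = 0.3). The Gini index, which is 0 when all guides are equally abundant and approaches 1 when a single guide takes every read, was 0.611 ± 0.011 (SD, n = 3) in controls and 0.645 ± 0.013 (SD, n = 3) after irradiation (exact p = 0.1). The top 1% of sub-library A guides held 8.26% ± 1.31 and 8.69% ± 0.347 of its reads (SD, n = 3 each; exact p = 0.7). Without irradiated replicate 1 the Gini difference of 0.0264 had an exact p of 0.2. Leaving out single libraries moved the top 1% difference from 0.0301 percentage points without control replicate 2 to 1.18 without control replicate 1 (exact p = 0.1 for the latter).

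**Figure D2:**
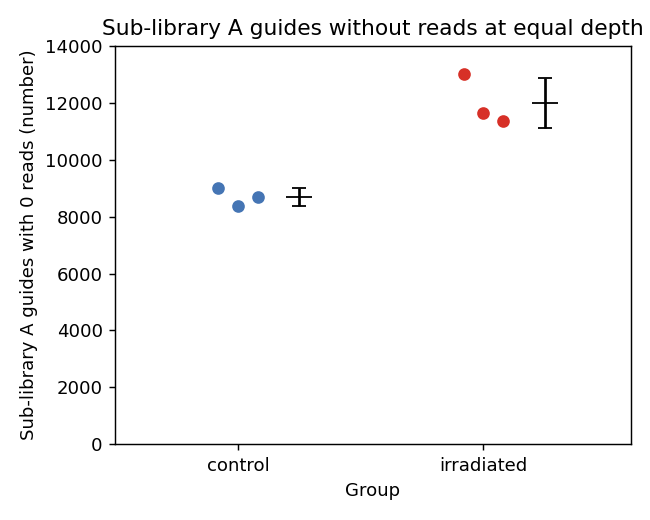
Points give the number of sub-library A guides with 0 reads in each library after thinning to equal depth, by group, with the mean and SD of 3 libraries drawn beside them. The 3 irradiated libraries lie between 11348 and 13012, above the 3 controls between 8389 and 9002.

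Over all guides as designed, missing guides numbered 6323 ± 2665 in controls and 9560 ± 1499 after irradiation (SD, n = 3 each; exact p = 0.2). Their Gini index was 0.593 ± 0.049 and 0.622 ± 0.008 (SD, n = 3 each; exact p = 0.4). The top 1% of all guides held 6.70% ± 0.628 and 7.33% ± 1.28 of the reads (SD, n = 3 each; exact p = 0.6). Leaving out single libraries moved the difference in missing guides, irradiated minus control, from 2036 without control replicate 2 to 4671 without control replicate 1, and that in the Gini index from 0.00738 to 0.0557 for the same libraries. Without control replicate 1 both reached an exact p of 0.1, the smallest possible, as did the top 1% difference of 1.36 percentage points without irradiated replicate 3. That difference was smallest, at 0.180 percentage points, without irradiated replicate 1. In sub-library B, 767 ± 1186 guides were missing in controls and 1503 ± 2082 after irradiation (SD, n = 3 each; exact p = 0.6). Single libraries ranged widely there, from 19 missing sub-library B guides in control replicate 1 and 20 in irradiated replicate 3 to 2135 in control replicate 3 and 3883 in irradiated replicate 2. The Gini index of sub-library B was 0.326 and 0.328 in the 2 libraries with few sub-library A reads and 0.502 to 0.609 in the other 4.

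Across all guides, 1 guide passed the test for a change in abundance after irradiation. HGLibA_08317 (TACCGCTGCATGATCAGCTA) fell by 8.42 on the log2 scale (SE 0.570; adjusted p = 0.0159, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It held 3207, 8205 and 14170 reads in the 3 controls and 21, 32 and 15 in the 3 irradiated libraries. Of 110895 guides tested, 0 passed as higher and 1 as lower at an adjusted p of 0.05, and DESeq2 called 11 higher and 1 lower. In the edgeR fit 174 higher and 27 lower guides had an unadjusted p under 0.05. That is far fewer than a share of 0.05 of the tested guides, which unchanged guides would give. The fitted coefficient of variation was 0.993, against 0.481 without control replicate 1 and irradiated replicate 3. Few calls therefore do not show that few guides changed. Without irradiated replicate 1 the adjusted p of HGLibA_08317 was 0.195, and with scaling to the closing run of guides shared by both sub-libraries it was 0.0799, so no guide passed as lower in either setting. Without control replicate 1 and irradiated replicate 3, both low in sub-library A, 74 guides were higher and 2 lower, a setting chosen after seeing the data. In simulated counts with the same depths and 1 spread per guide for both groups, this design recovered 2% of guides changed 8-fold and 6% of guides changed 16-fold. It also called 1 of 110695 unchanged guides, as many as the guides called in the data. Simulated guides varied independently, unlike the sub-library A guides that were scarce together in control replicate 1 and irradiated replicate 3. These rates may therefore not carry over to the data.

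Sub-library A alone, a restriction chosen after seeing the data, gave 751 guides higher and 200 lower among 52835 tested (edgeR quasi-likelihood test, adjusted p 0.05). In simulated counts of sub-library A, 25 of 139 calls (18.0%) fell on unchanged guides, above the nominal 5%. That simulation gave both groups 1 spread per guide. In the data the coefficient of variation between libraries was 0.267 in controls and 0.490 in irradiated libraries. The simulated share of false calls therefore need not hold for the guides called in the data. In each called guide all 3 irradiated libraries lay on the same side of all 3 controls, as did 25.7% of the tested guides. Chance gives 10% only if all libraries have the same spread. The unequal spread of the 2 groups can raise this share without any shift, so 25.7% cannot be read against 10%. The median log2 fold change was 1.55 among the higher guides and -2.72 among the lower ones. More than 4-fold changes were found in 237 higher and 136 lower guides, and more than 16-fold changes in 56 and 74. Of the called guides, 8 higher ones had no read in any control and 34 lower ones had no read in any irradiated library, and medians and counts were unchanged with these guides at the bound of 3 reads over the group. The higher guides took 1.70% ± 0.077 of sub-library A reads in controls and 4.03% ± 0.135 after irradiation (SD, n = 3 each). The lower guides took 0.504% ± 0.126 and 0.104% ± 0.008 (SD, n = 3 each). The called guides were chosen by the test on these same libraries. Their shares, fold changes and separation of groups follow from that choice and are not separate support.

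**Figure D3:**
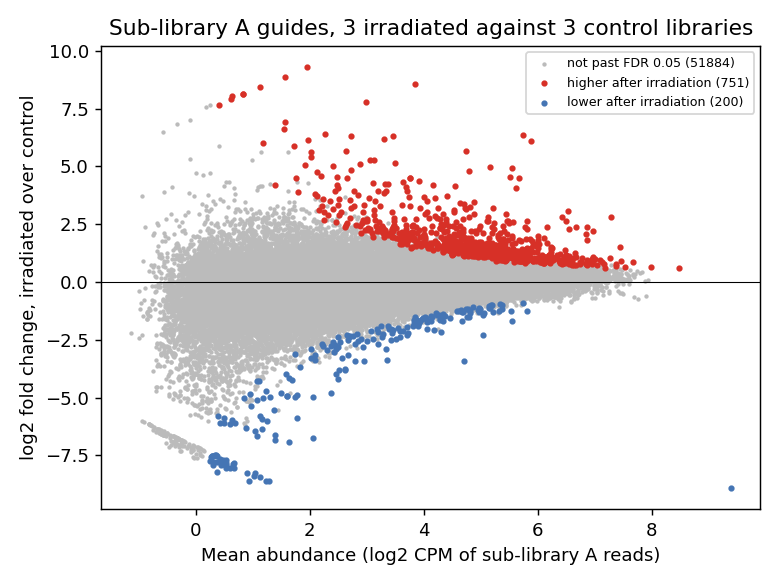
Each point is 1 of 52835 sub-library A guides, with its mean abundance (log2 CPM) on the horizontal axis and its log2 fold change, irradiated over control, on the vertical axis. The 751 guides higher after irradiation are red, the 200 lower ones are blue, and the isolated blue point at high abundance is HGLibA_08317.

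HGLibA_39471 (CCGAAAGAGTACGACATCCC) rose from 2.66 ± 3.54 to 48.6 ± 8.24 CPM of sub-library A reads (SD, n = 3 each), a log2 fold change of 5.65 in the fit, which weighs libraries by depth (SE 0.673; edgeR adjusted p = 5.07e-04). Its control mean rests on 8 reads in control replicate 1, or 6.73 CPM, where control replicates 2 and 3 had 0.957 and 0.290 CPM. The log2 fold change was 6.43 without control replicate 1 and 4.69 without control replicate 3. HGLibA_01880 (GAGATGATCCAGCGTCTGTA) had 2 reads over the 3 controls and 850 over the 3 irradiated libraries. Its ratio of pooled frequencies was 392 (95% counting interval 108 to 3241), and it passed in sub-library A with an edgeR adjusted p of 3.58e-05. Its fitted log2 fold change there was 9.41 without control replicate 1 and 7.51 without control replicate 3, around 8.55 with all libraries. In the edgeR fit over all guides neither passed, with log2 fold changes of 5.93 and 8.50 and an adjusted p of 1 each. Over all guides both passed with DESeq2 (adjusted p = 5.21e-04 and 1.76e-04) and with edgeR without both libraries low in sub-library A (adjusted p = 0.00779 and 0.00964). Over all their alternatives the adjusted p ranged from 9.63e-06 to 1 for HGLibA_39471 and from 5.87e-07 to 1 for HGLibA_01880. HGLibA_08317 fell from 1374 ± 1150 to 3.74 ± 3.71 CPM (SD, n = 3 each; edgeR adjusted p = 1.51e-05). Its log2 fold change in sub-library A was -8.91, and -8.12 without control replicate 1 and -9.61 without irradiated replicate 3. HGLibA_14242 (GAGCTTGGAGCGCGAGCGGG) had 94 reads over the 3 controls and 0 after irradiation, which made it at least 34.0-fold lower against a floor of 3 reads over the group (edgeR adjusted p = 0.0233 in sub-library A and 1 over all guides). Leaving out any single control ended this call, with an edgeR adjusted p of 0.116, 0.0910 and 0.0558 without control replicates 1, 2 and 3, as did leaving out both libraries low in sub-library A (0.151).

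The count of called sub-library A guides fell when any single control was left out. It was 232 higher and 13 lower without control replicate 1, 207 and 13 without control replicate 2, and 223 and 13 without control replicate 3. Without irradiated replicate 1 it was 1036 higher and 524 lower, without irradiated replicate 2 it was 813 and 276, and without irradiated replicate 3 it was 749 and 237. Scaling by total counts alone shifted the median log2 fold change of the tested guides from 0.00 to -0.12 and gave 501 higher and 267 lower guides. With both libraries that were low in sub-library A left out, 108 guides were higher and 4 lower. The coefficient of variation between libraries was 0.267 within controls and 0.490 within irradiated libraries, a difference that was not tested.

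In sub-library B the fit of all 6 libraries called 0 guides among 53917 tested (edgeR quasi-likelihood test), and DESeq2 was not run on this part. In that fit 368 higher and 150 lower guides had an unadjusted p under 0.05, again fewer than the share of 0.05 that unchanged guides would give. Measured against control replicate 3 and irradiated replicate 2, an excess made up 95.93% of sub-library B reads in control replicate 1 and 93.35% in irradiated replicate 3. These libraries of opposite groups held nearly the same sub-library B reads (r = 0.988). The 0 calls therefore do not show that no sub-library B guide changed. Without control replicate 1 and irradiated replicate 3, a setting chosen after seeing the data, 35 sub-library B guides were higher and 1 lower. The remaining libraries were still uneven. By the same measure, the excess made up 28.5% of sub-library B reads in control replicate 2 and 8.94% in irradiated replicate 1. The fit did not account for this, so these counts cannot be credited to irradiation alone. Leaving out a further library left 1 library in its group, whose spread was then assumed to equal that of the other group. These fits called 46 higher and 0 lower guides without control replicate 2, and 269 and 388 without control replicate 3. Without irradiated replicate 1 they called 1150 and 2091, and without irradiated replicate 2 they called 508 and 906.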

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

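The restriction to a sub-library and the fits without the 2 libraries low in sub-library A were chosen after seeing the data. Depth limited sub-library A most in those 2 libraries, and with 3 libraries per group no exact test of a per-library value could go below 0.1. Over all guides the main count of 0 higher and 1 lower became 11 higher with DESeq2, 74 higher and 2 lower without both low libraries, 0 lower with scaling to the closing run and 0 lower in sub-library B alone. It became 751 higher and 200 lower in sub-library A alone. Leaving out single libraries gave 0 to 1 lower guides over all guides. Within sub-library A the 751 higher and 200 lower guides became 1908 and 1035 with DESeq2, 4809 and 3503 at an adjusted p of 0.25, and 108 and 4 without both low libraries, where fewer samples were fitted. Leaving out single libraries gave 207 to 1036 higher and 13 to 524 lower guides. Of the 951 called sub-library A guides, 949 were also called by DESeq2, 700 with total counts only and 111 without both low libraries, in each case with 0 in the opposite direction. In sub-library B, 35 higher and 1 lower guides without both low libraries became 0 and 0 with all 6 libraries, and leaving out a further library gave 46 to 1150 higher and 0 to 2091 lower. The cause was not tested.

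HGLibA_08317 passed in 32 of 34 alternatives, HGLibA_01880 and HGLibA_39471 in 18 of 34 each and HGLibA_14242 in 11 of 32. These refit the same reads and are not separate support. None reversed direction. The adjusted p of HGLibA_08317 reached 0.195. Its lowest, 1.98e-109, came with the replicate block over all guides (0.0159 without it).

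The mean correlation within controls moved from 0.511 to 0.907 in sub-library A and 0.906 there at equal depth, and within irradiated libraries from 0.493 to 0.853 and 0.879. The equal-depth values also took guides that the read filter left out. For sub-library B, leaving out single libraries gave differences, irradiated minus control, of -454.8 to 1477 missing guides, -0.0274 to 0.135 in Gini index and -0.421 to 2.16 percentage points in the top 1%. The first turned negative without irradiated replicate 2, the Gini index without control replicate 1 and (-0.00541) without irradiated replicate 2. The top 1% turned negative without control replicate 1, irradiated replicate 1 (-0.0416) and irradiated replicate 2 (-0.0124). The other 66 alternatives for differences in representation kept their direction, 11 correlations moved by less than their spread, and 52 counts of guides stayed within 1.5 times the main count.

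For libraries of the same replicate number, deviations from the group means correlated at -0.800, 0.718 and -0.932 over all guides. In sub-library A they correlated at -0.056, 0.042 and -0.088. Control replicate 1 was closest to irradiated replicate 3, at 0.957 over all guides. The values over all guides thus followed the scarcity of sub-library A in these libraries, which were also shallow within sub-library A. They show no pairing by replicate number but cannot exclude it. With the replicate block the fit over all guides called 3 higher and 1 lower guides, and the fit of sub-library A called 581 and 114.

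The planned tests of enriched and depleted genes, gene lists and essential-gene values were not run in any setting, as the files do not pair guide IDs with genes.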

Other observations

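Among sub-library A guides, base composition went with small differences. The median log2 fold change after irradiation was 0.01 in 9195 guides of up to 40% GC, 0.02 in 31929 guides of 45 to 60% GC and -0.06 in 11711 guides of 65% GC or more. Guides called higher made up 1.56%, 1.49% and 1.14% of these classes, and guides called lower 0.294%, 0.391% and 0.410%. The 1000 closing-run sequences, measured over the 4 libraries not low in sub-library A, had a mean log2 fold change of -0.16, and random pairs of a sub-library A and a sub-library B guide of the same abundance had -0.16. None of these differences was tested.

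Of the tests below, those on the 2 libraries low in sub-library A and the comparison of joint losses with control pairs were chosen after the result was seen. Of the others, the minimum in the first test of shared losses and the matching in the test of the closing run were changed after a first value was seen, and the Poisson interval in the test of neighbouring IDs was added then.

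Control replicate 1 and irradiated replicate 3 held few sub-library A reads and nearly the same sub-library B reads. The tables argued against irradiation as the cause, since 1 of the 2 libraries was a control. A swap of labels between the groups could not by itself make sub-library A scarce. Each library was also closer to its own group in sub-library A at equal depth, but the smaller margin of mean r, 0.00924 for irradiated replicate 3, has no interval. Fewer cells with sub-library A guides stays open: the sub-library B guides of these libraries correlated 0.271 better with each other than with any other library, which cultures of their own groups would not give, but a separate cell stock with evenly represented sub-library B guides would. DNA or reads of an evenly represented sub-library B pool stays open as a candidate source: the floor of sub-library B reads differed from the excess over sub-library A by up to 0.0847, above the 0.05 set for a match and below the 0.1 set against it. On 1482 sub-library B guides without reads in control replicate 3 and irradiated replicate 2, control replicate 2 held 28.3% and irradiated replicate 1 held 9.60% of the level of the low libraries where their excess of sub-library B reads predicted 28.5% and 8.94%, and this difference of at most 0.656 percentage points is consistent with the same pool in those 2 libraries, as a hypothesis found and tested on the same data.

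More sub-library A guides lacked reads after irradiation at equal depth. Sequencing depth is argued against as the cause, since the lowest irradiated library still lay 2346 guides above the highest control at equal depth. A loss shared by the irradiated cultures before they were separated stays open: 773 guides were missing from all 3 irradiated libraries where independent losses at the same control abundance gave 341 (93 and 18.7 with at least 3 predicted reads, 0 and 0.00546 with at least 10), and this ratio of 2.27 met the 1.5 set beforehand for a shared loss, but error in that abundance makes losses coincide as well, so the ratio cannot be read against 1. With the abundance taken from 1 deep control, the odds ratio of joint losses was 2.94 to 3.09 in irradiated pairs, 1.87 and 2.09 in control pairs and 1.57 to 2.11 in mixed pairs, and the smaller quotient of the mean of irradiated pairs over the control pair, 1.44, lay below the 1.5 set for this replacement test. Selection against guides after irradiation would also give shared losses and stays open, as untested.

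Guides called in sub-library A numbered 951, and the highest count of the other splits of the 6 libraries was 36; over all guides the numbers were 1 and 0, and in both cases 1 of the 10 splits, the real one, reached the count, too few splits for a share under 0.05. For the called guides, selection on a target shared by neighbouring IDs and calls scattered over IDs cannot be told apart: 8 pairs of consecutive IDs were called in the same direction, 0.83 times the 9.63 of shuffled calls, with a 95% shuffle range of 4 to 16. That met the bound set beforehand against shared targets, a ratio under 1.5 inside the shuffle range, but not by more than its spread, since the exact Poisson interval of 8 pairs reaches 1.64 times the shuffled mean. Over the wider set of 9429 guides with an unadjusted p under 0.05 the pairs numbered 752 against 726.6 shuffled (permutation p = 0.162). There the ratio was 1.035 (95% Poisson interval 0.962 to 1.112), wholly below 1.5. The wider set also holds guides that were not called. Selection on few targets would add few pairs to so many and leave the ratio below 1.5. The wider set therefore does not decide whether called neighbours share targets. Drift that does not depend on the target may account for part of the spread, since the SD of log2 fold change of the closing-run sequences, taken as non-targeting from the published library, was 1.05 times that of random pairs of the same abundance (95% bootstrap interval 0.985 to 1.11), over the 4 libraries not low in sub-library A. Selection by irradiation stays open for single guides, as the files do not say which guides share a gene.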
